A study of Homo sapiens with 2 samples.

How the data were processed

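Gene expression was measured in CaSki cells, an established human cervical cancer line that carries human papillomavirus type 16 (background knowledge, not stated in the labels). Per the labels' protocols, cells were transduced with a lentivirus encoding a short hairpin RNA against the long non-coding RNA NCK1-AS1 or with a control, resistant cells were selected with puromycin, and biotin-labelled cDNA was made from 250 ng of total RNA for Affymetrix arrays. The control array is described as wild-type cells in 1 label and as negative control cells in another. Whether it carried a control hairpin is therefore not settled by the labels. There were 2 arrays, 1 per group, with 1 column of values each.

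The authors deposited 1 log2 level per transcript cluster (an array feature set that summarises all probes of a transcribed region). Per the submitters' processing notes the values came from RMA, a method that corrects background, normalizes the arrays to a common distribution and summarises probes by median polish. The RMA version, the annotation build and any filter are not given in the sources used here. The log base is not written in the file, and log2 was read from RMA and from a range of 0.195 to 12.7 in the control column and 0.186 to 12.7 in the knockdown column. The quartiles were 2.19, 3.53 and 5.02 in the control and 2.23, 3.57 and 5.05 in the knockdown. The deposited values carry no detection call, scan date or probe-level signal, so a level cannot be called above or below background, and the number of arrays limits the precision. Of 65528 transcript clusters, 10292 (15.7%) held exactly equal values on both arrays. That share was 30.7% in the dimmest of 5 equal groups of clusters and 3.87% in the brightest.

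Genes were named through the platform annotation table. A single gene symbol was given for 22686 clusters, several symbols for 1385, and 41457 were unnamed here. Symbols were updated through the Entrez identifier or a unique synonym in the reference gene table of assembly GRCh38.p14, which changed 295 of them. Where a gene had several clusters, the brightest over both arrays was used. This left 22324 genes, of which 345 had more than 1 cluster. In the 89 genes with 2 or more clusters at or above the median gene level, the median gap between their differences was 0.089 and the largest 0.70. The build behind the array annotation is not given in the sources used here, so no coordinates are printed.

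The measure throughout is the log2 difference, knockdown minus control. With 1 array per group there is no replicate check, no standard error and no test, and no p-value is given. Changes are described by size. A gene is said to have risen or fallen if it differed by at least 2-fold (1 on the log2 scale) and its brighter array was at or above 4.72, the median level of all genes, which 11459 genes reached. Genes below that size are given as values. For each of 29 gene lists, the median difference was set against the medians of 10000 random lists of the same size drawn from the same 20 bins of mean level, and a list outside their central 95% was called apart. The percentile describes these 2 arrays only. It does not allow for genes of a pathway that vary together from culture to culture.

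The gene lists, the size threshold, the alternatives and the rule for named genes were fixed before the data were examined. Named were NCK1, CDK1, the 15 highest and the 15 lowest genes at or above the median level (leaving out small RNAs, immune receptor segments and clone names), and in each list up to 4 members at or above that level with the largest absolute difference. Genes named outside that rule are marked as chosen after their values were seen. The design also planned a value for NCK1-AS1, which could not be given because 0 named clusters carried its symbol or its newer symbol NCK1-DT.

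The alternatives were subtraction of the median difference, quantile normalization of both columns, removal of the trend over level by loess (span 0.2), the mean or the largest difference of a gene's clusters, other filters on dim genes, 32 added to the linear values, size thresholds of 1.5-fold and 3-fold, the inclusion of clusters that name several genes, and 10 level bins. The choices added after the data were seen were random lists of protein-coding genes, lists without members at equal values, and lists without members shared with another list. Gene families defined by symbol were also chosen after the list results were seen, and were recomputed under the first 3 alternatives.

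The method was tested on simulated data made from these arrays, with differences shuffled within level bins over 22324 genes. Over 10 shuffles of the 29 lists, 6.9% of unshifted lists, 75.5% of lists shifted by 0.1 and 98.6% of lists shifted by 0.2 were called apart. Of 200 genes among the 11459 changed by 1.5 on the log2 scale, 99% passed the 2-fold size, against 56% of genes changed by 1. Of the unchanged genes, 3 passed it. The shuffled differences hold the large ones of these arrays, so these 3 are no estimate of false calls. Calculations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, statsmodels 0.14.6 and matplotlib 3.10.9.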

Results

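Whole-transcript arrays were hybridised with RNA from CaSki cervical cancer cells to compare cells with a hairpin-mediated knockdown of the long non-coding RNA NCK1-AS1 with control cells, which the labels describe both as wild type and as negative control. Each group held 1 array, so each difference below compares 2 RNA samples and has no replicate error. The arrays correlated at r = 0.996 across the 22324 genes, which are not independent replicates. The SD of the differences was 0.17 and their median 0.0079 (log2, knockdown minus control). Among genes at or above the median level, the central 95% of differences lay between -0.37 and 0.30.

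The targeted RNA could not be followed in these data, since 0 named transcript clusters carried the symbol NCK1-AS1 or NCK1-DT. The knockdown is therefore taken from the labels. NCK1, the SH2 and SH3 adaptor gene that lies next to NCK1-DT on chromosome 3 in the GRCh38.p14 gene table, had a level of 5.77 in the control and 5.69 in the knockdown, a difference of -0.084. The neighbouring SLC35G2, named after its value was seen, differed by -0.10. Of 14 measured genes of this region, 0 differed by 2-fold. Among the 9 at or above the median gene level, the largest differences were -0.20 for MSL2, -0.17 for IL20RB, -0.11 for STAG1 and -0.10 for ARMC8. The dimmer PPP2R3A at -0.37 and IL20RB-AS1 at 0.27, named after their values were seen, differed by more. The median of -0.050 lay at percentile 4.08 of the random lists, inside their central range, but at 1.74, below it, with 32 added to the linear values.

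Among the 11459 genes at or above the median level, 4 fell by at least 2-fold in the knockdown and 0 rose by that much. With 32 added to the linear values, which shrinks differences of dim genes, 1 passed that size, and the difference of CDH1 was -0.93 and the difference of MUC1 was -0.79. CASP14, a caspase of cornifying keratinocytes, fell from 8.53 to 7.21, which is 2.49-fold. CDH1, which encodes the adherens junction protein E-cadherin, fell from 7.11 to 5.85, or 2.40-fold. MUC1, a membrane mucin of glandular and squamous epithelia, fell from 7.26 to 6.23, or 2.05-fold. The fourth was the microRNA gene MIR548W at -1.08, which is outside the naming rule and was named after its value was seen. Its level of 4.83 in the control was just above the median of 4.72, and its 3.75 in the knockdown was below it. At 1.5-fold, 46 genes were lower and 11 higher.

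The next lowest genes lay between -0.96 and -0.81. They held ALDH1A3, a retinaldehyde dehydrogenase, at -0.96 and RARRES1, a retinoid-responsive gene, at -0.84. PTGS1, the constitutive cyclooxygenase, differed by -0.96, the adhesion gene MPZL2 by -0.92, C1orf116 by -0.91 and the bitter taste receptor TAS2R30 by -0.90. XPR1, a phosphate exporter, differed by -0.89, NDRG1 by -0.87, TCP11L2 by -0.86, the serotonin receptor HTR1D by -0.84, TNFSF10, which encodes the death ligand TRAIL, by -0.82, and BNC1, a basonuclin of squamous epithelium, by -0.81. Among genes in the same bin of mean level, at most 0.358% differed by as much as any of these 15. A small share follows from their choice as the lowest genes.

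No gene was 2-fold higher. LOC151760 at 0.84 and the small nucleolar RNA SNORD82 at 0.82 were highest, both outside the naming rule and named after their values were seen. Leaving out small RNAs and clone names, the 15 highest genes lay between 0.51 and 0.73. LINC02582 led them at 0.73, followed by PI3, the epithelial protease inhibitor elafin, at 0.69, SOCS1, a suppressor of cytokine signalling, at 0.66, and FN1, fibronectin, at 0.63. In the control, LINC02582 at 4.11 and SOCS1 at 4.46 lay below the median gene level of 4.72. FN1 lay just above it at 4.93, and PI3 was brighter at 6.87. Mitochondrial genes among the 15 were SLIRP, a mitochondrial RNA-binding protein, at 0.57 and ATP5MJ, an ATP synthase subunit, at 0.55. ZNF593 was at 0.54. The lysosomal protease gene CTSC was at 0.52, RPPH1, the RNA of ribonuclease P, at 0.52 and PRG4 at 0.51. The pseudogenes RPS4XP21 at 0.61, FABP5P7 at 0.59, RPL13AP6 at 0.55 and FABP5P1 at 0.53 resemble their parent genes closely, so their signal cannot be assigned to them with certainty. The hair keratin-associated gene KRTAP10-2, at 0.54, belongs to a family known from the hair shaft.

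**Figure D1:**
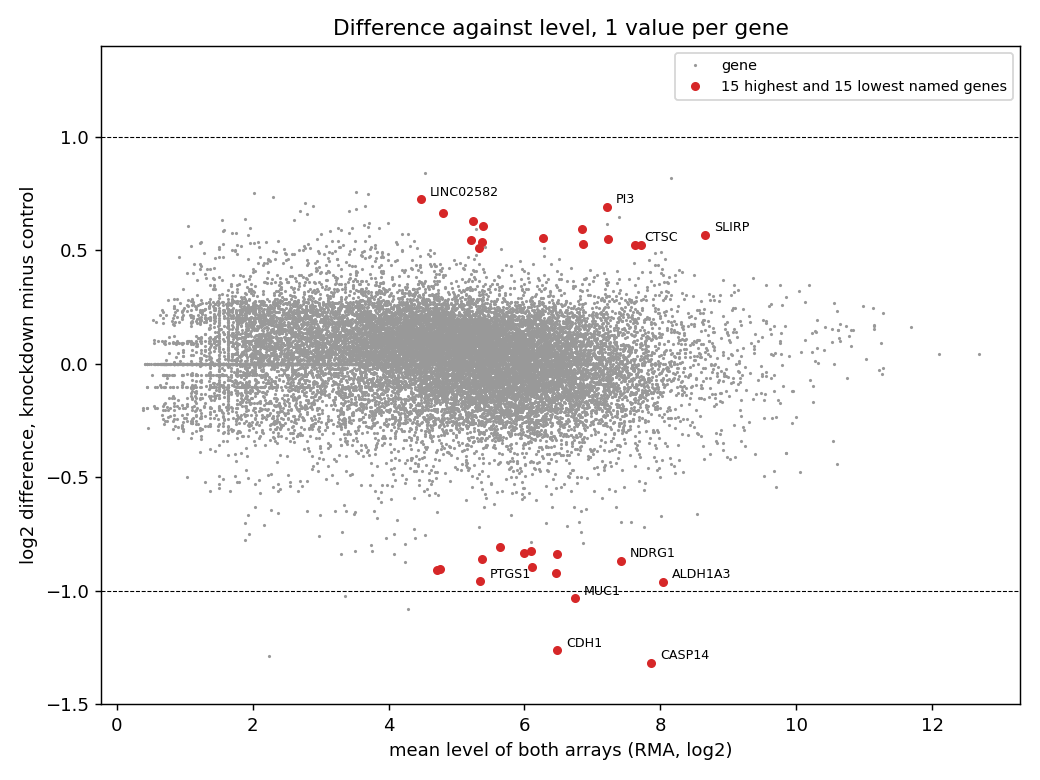
Log2 difference (knockdown minus control, 1 array each) of each gene against its mean RMA level on both arrays; each grey point is a gene, red points are the 15 highest and 15 lowest named genes, and dashed lines mark 2-fold. CASP14, CDH1 and MUC1 lie below the lower line at -1.32, -1.26 and -1.03, and no red point reaches the upper line.

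The hypoxia and glycolysis list was lower as a group. Of 34 measured members, 32 were lower in the knockdown, 2 were equal and 0 were higher. The median was -0.37, a fold of 1.29, below all 10000 random lists (central range -0.062 to 0.070). No member differed by 2-fold, and 5 did by 1.5-fold. These were NDRG1 at -0.87, the mitophagy gene BNIP3 at -0.72, PDK1, a kinase that restrains pyruvate dehydrogenase, at -0.70, PFKFB3, a regulator of glycolytic flux, at -0.63, and MXI1 at -0.59, the last named after its value was seen. Further members singled out after their values were seen were the angiogenic factor VEGFA at -0.52, the glucose transporter SLC2A1 at -0.38 and hexokinase HK2 at -0.38, against -0.069 for lactate dehydrogenase LDHA and -0.062 for TPI1.

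Genes of epithelial adhesion were also lower as a group. In this list 25 of 31 measured members were lower and 6 higher, with a median of -0.23 (percentile 0, random range -0.043 to 0.083), or -0.14 with 32 added to the linear values. CDH1 fell by 2-fold or more. The simple-epithelium keratin KRT19 differed by -0.65, the tight junction claudin CLDN1 by -0.54 and P-cadherin, CDH3, by -0.47. Among members at or above the median level, 24 were lower and 1 was higher, CLDN3 at 0.32, which was singled out after its value was seen. The basal squamous list had a median of -0.084 over 14 measured genes (percentile 1.01), or -0.044 with 32 added, with ITGB4 at -0.57, SFN at -0.35, TRIM29 at -0.29 and DST at -0.24 among those that differed most. Its 9 members at or above the median level had a median of -0.23.

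The mesenchymal list was not apart from random lists, with a median of 0.066 over 28 measured genes at percentile 87.3. FN1 was at 0.63, the transcription factors SNAI1 and SNAI2 at 0.41 and 0.25, and the collagen cross-linking enzyme LOX at -0.48. VIM, chosen after its value was seen, was dim on both arrays at 3.42 and 3.54. The list of matrix proteases and invasion genes had a median of 0, at percentile 32.2, with ITGA5 at -0.50, MMP14 at -0.46, TIMP3 at -0.40 and CD44 at -0.36. Its median was -0.15 over the 19 members at or above the median gene level, at percentile 0.02, outside the random range.

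**Figure D2:**
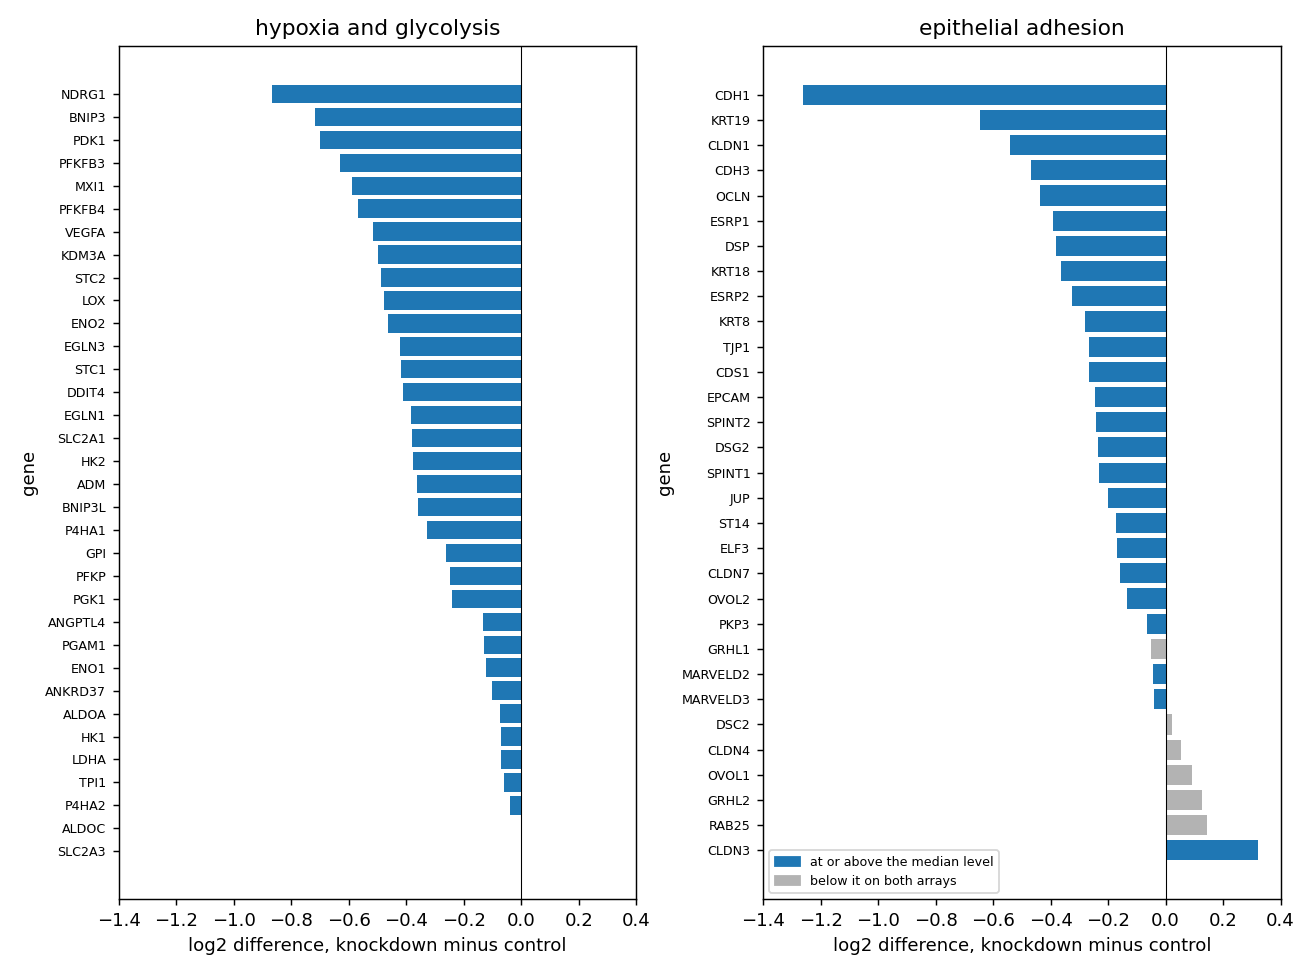
Log2 difference (knockdown minus control, 1 array each) of every measured member of the hypoxia and glycolysis list and of the epithelial adhesion list; bars start at 0, blue bars are genes at or above the median gene level on the brighter array, and grey bars are dimmer. In the first list 32 of 34 bars point left and 2 are at 0, and in the second 25 of 31 point left with CDH1 longest at -1.26.

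Cytosolic ribosomal protein genes were higher in the knockdown in all 24 measured members. Their median was 0.23, a fold of 1.17, above all 10000 random lists, with RPL30 at 0.39, RPL19 at 0.38, RPS28 at 0.35 and RPL24 at 0.31. These transcripts are short, and transcript length and GC content were not analysed here. Heat shock and chaperone genes had a median of 0.21, and 15 of 16 were higher, led by HSPB1 at 0.46, the HSP90 co-chaperone FKBP4 at 0.41, HSPE1 at 0.34 and HSP90AB1 at 0.32. Oxidative phosphorylation genes had a median of 0.15, and 24 of 27 were higher, led by NDUFA1 at 0.36, NDUFA9 at 0.33, NDUFA2 at 0.28 and CYC1 at 0.28. No member of these lists differed by 1.5-fold. Genes known mainly from other tissues stood higher too: in the silent tissue-restricted list 37 of 57 were higher, 16 equal and 4 lower, with a median of 0.10 at percentile 99.8, which was 0.048 after removal of the level trend and 0.023 with 32 added. The 12 of them at or above the median level were all higher, with a median of 0.15, led by the olfactory receptor OR10H1 at 0.43, SST at 0.28, KRTAP5-5 at 0.23 and CRYGD at 0.20. Only 6 of these 12 reached that level on both arrays, and as a list these 6 still lay above the random range. The others reached it on the knockdown array alone, so their being higher follows from the filter.

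The other lists above the random range had medians of at most 0.14 over all measured members, against 0.10 for the silent list. NRF2 targets, squamous differentiation and Wnt and Notch targets exceeded the silent list in this, and the others did not. NRF2 targets had a median of 0.14 (percentile 99.99, 19 of 25 higher), or 0.086 with 32 added, with the aldo-keto reductase AKR1C2 at 0.41, haem oxygenase HMOX1 at 0.32, PIR at 0.30 and the exception ALDH3A1 at -0.30. Squamous differentiation genes had a median of 0.14 (percentile 99.98, 25 of 35 higher), or 0.093 after removal of the level trend and 0.039 with 32 added, with PI3 at 0.69, MAL at 0.29, CSTB at 0.20 and the kallikrein KLK10 at -0.39. Of these 35 genes, 23 were dim on both arrays. CASP14, which also belongs to cornification, was not on that list. Sterol and fatty acid synthesis genes had a median of 0.087 (percentile 99.1, 19 of 27 higher), with HMGCS1 at 0.40, NSDHL at 0.33, SQLE at 0.31 and IDI1 at 0.29, all of the cholesterol branch. Wnt and Notch targets had a median of 0.11 (percentile 99.3) with 24 of 32 higher. It was 0.070 after removal of the level trend and 0.041 with 32 added, and the call was lost without dim members. The member that differed most was WNT5A at -0.38, beside FZD7 at 0.19, NKD1 at 0.18 and DTX1 at 0.16. The unfolded protein and amino acid response list stood at the edge of the range, with a median of 0.080 against an upper bound of 0.079, a call lost under 4 alternatives, and held STC2 at -0.49 and DDIT4 at -0.41, which are also on the hypoxia list, beside SHMT2 and CEBPB, both at 0.37.

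Cell cycle genes were not apart from random lists. CDK1, the mitotic kinase, had levels of 6.04 and 6.09, a difference of 0.051. The G2/M and mitosis list had a median of -0.062 over 39 genes (percentile 5.22), with CKS2 at 0.44 and CCNB1 at 0.30 against ASPM at -0.25 and KIF11 at -0.24. The list of G1/S and DNA replication had a median of -0.049 over 38 genes (percentile 7.88), with POLA1 at -0.40, GINS3 at -0.19, E2F2 at -0.16 and CCNE2 at -0.16. Replication-dependent histones had a median of 0.057 at percentile 81.6, over 12 of 26 genes, with H2BC14 at 0.43, H1-2 at 0.17, H4C3 at -0.13 and H2BC9 at 0.11. The p53 target list had a median of 0.058 (percentile 89.9), with PPM1D at -0.20, DDB2 at -0.19, AEN at 0.19 and ZMAT3 at -0.17. Apoptosis regulators had a median of 0.0084 (percentile 55.1), and only TNFSF10 passed 1.5-fold, at -0.82. BIRC2 was at -0.43, cytochrome c, CYCS, at 0.37 and APAF1 at -0.25.

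**Figure D3:**
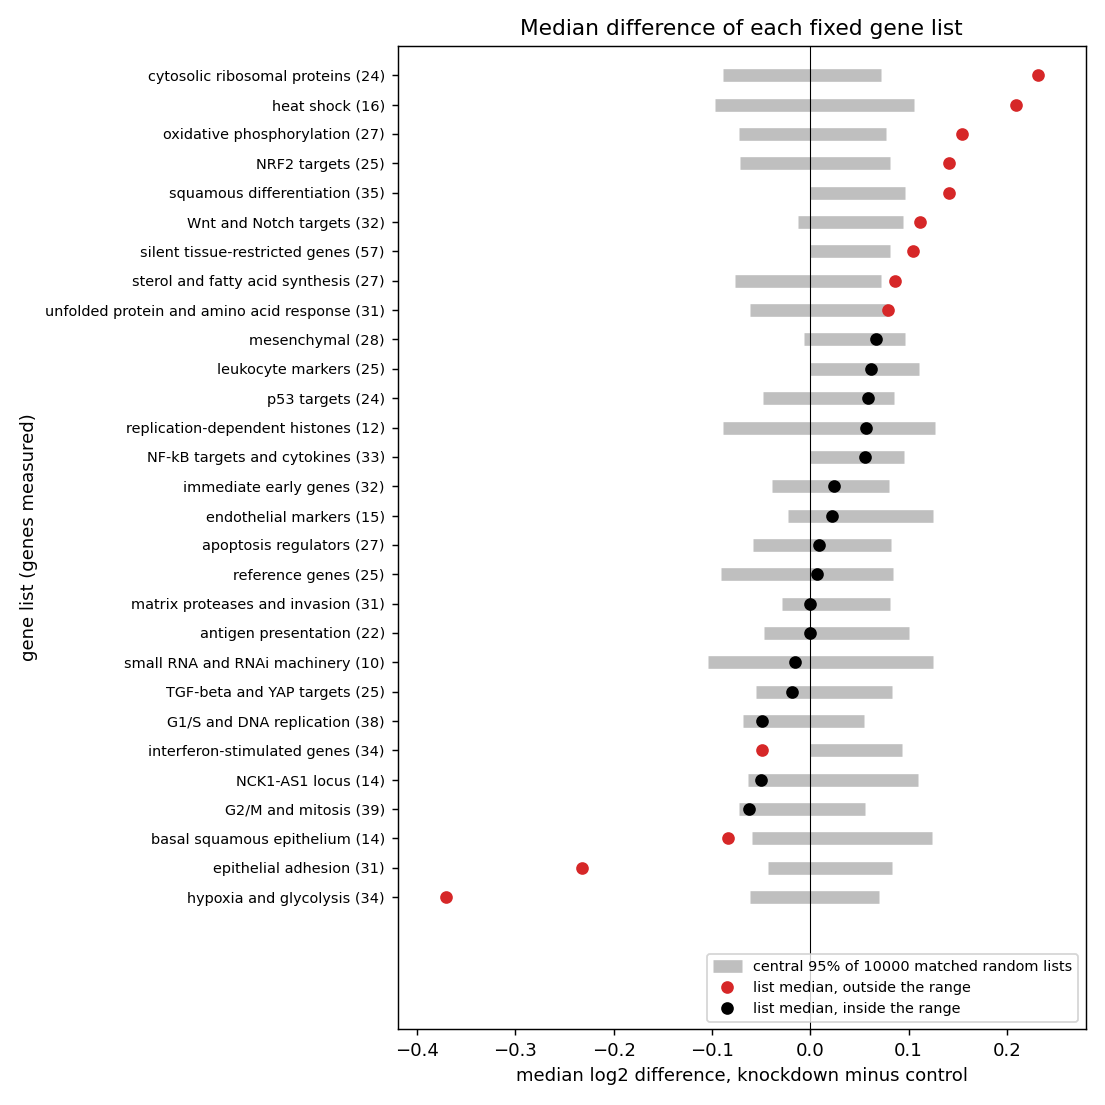
Median log2 difference (knockdown minus control, 1 array each) of each of the 29 gene lists, with the number of genes measured in brackets; grey bars are the central 95% of 10000 random lists matched on level, red points lie outside it and black points inside. The 4 red points on the left are hypoxia and glycolysis at -0.37, epithelial adhesion at -0.23, basal squamous epithelium at -0.084 and interferon-stimulated genes at -0.050, and 9 red points lie on the right.

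Of the immune-related lists, interferon-stimulated genes had a median of -0.050 (percentile 0.1), or -0.084 after removal of the level trend and -0.013 with 32 added, with 18 of 34 lower, 11 higher and 18 dim on both arrays. Its brighter members went both ways, with XAF1 at -0.39 against IFI6 at 0.35, BST2 at 0.28 and ISG15 at 0.28. Over the 16 members at or above the median gene level the median was -0.0086 and the list was no longer apart. It was 0.080 over the 13 with both levels at or above it. With the filter at the 75th percentile it was 0.28 over 3 genes, above the random range. The antigen presentation list had a median of -0.00081 (percentile 16.9), with TAPBP at -0.20, ERAP1 at -0.15, TAP2 at 0.12 and HLA-C at 0.11. NF-kB targets and cytokines had a median of 0.056 (percentile 82.7), with TNFAIP2 at -0.50, IL11 at 0.24, NFKB1 at -0.20 and TNFAIP3 at -0.18. The RNA interference machinery, which processes hairpin RNAs, had a median of -0.015 over 10 genes (percentile 28.1), with TNRC6A at -0.28, TARBP2 at 0.13, DICER1 at -0.11 and TNRC6C at 0.048.

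Immediate early genes had a median of 0.024 (percentile 61.9), with FOSL2 at -0.37, SPRY4 at 0.34, EGR1 at 0.27 and IER3 at -0.24. TGF-beta and YAP targets had a median of -0.019 (percentile 10.9), with AJUBA at -0.34, THBS1 at 0.28, ID2 at 0.27 and CCN1 at 0.23. Reference genes had a median of 0.0065 (percentile 64.2), with TFRC at -0.34, GPI at -0.26, PGK1 at -0.24 and EMC7 at 0.16; GPI and PGK1 are also on the hypoxia and glycolysis list. Leukocyte markers had a median of 0.062 (percentile 78.3), with CD14 at -0.26, NKG7 at 0.25, CORO1A at 0.21 and CD68 at -0.11. Endothelial markers had a median of 0.023 (percentile 53.1), with EGFL7 at 0.19, ENG at -0.058, ESAM at 0.023 and CLDN5 at 0.0079. In all, 13 of the 29 lists were apart. In shuffled data 6.9% of unshifted lists were. Shuffling breaks any tendency of pathway genes to vary together. That rate therefore does not show how many lists would be apart between cultures treated alike.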

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

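Transcript clusters without a gene name here were outside the gene comparison, and some of them differed by at least 2-fold. Among 8146 such clusters at or above the median gene level, 11 were at least 2-fold higher in the knockdown and 19 at least 2-fold lower. The 11 higher clusters, TC15001157.hg.1 and TC15001673.hg.1 among them, all held 1 pair of values, 4.04 in the control and 5.06 in the knockdown, a difference of 1.02, so they count as 1 signal. The 19 lower clusters held 8 distinct pairs of values, and 12 of them shared 1 pair. The lowest were TC09001235.hg.1 at -1.51 and TC03001865.hg.1 at -1.23. In all, 609 of the 8146 unnamed clusters shared both values with another, against 70 of 11552 clusters that name 1 gene, of which 0 were 2-fold higher and 5 lower. No 2 members of any of the 29 gene lists shared both values.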

How the results depend on the processing

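The random lists of protein-coding genes and the lists without equal-value or shared members were chosen after seeing the data. No paired analysis was possible because each group held 1 array, and for the same reason no replicate could be left out and no other split of the samples exists. The planned NCK1-AS1 value could not be computed under any setting, and lists carry no filter on dim genes, so leaving it off alters only the gene counts. Of the list medians under the alternatives, 303 moved by less than 0.1 and 11 by at least that much. The other 2 were those of a list called apart that changed sign; medians of lists not called apart were given no direction, and some of them changed sign too. The count of genes at least 2-fold lower was 4, but 1 with 32 added to the linear values, where the difference of CDH1 was -0.93 and the difference of MUC1 was -0.79. At 1.5-fold the counts were 46 lower and 11 higher, and at 3-fold 0 were lower; under the other settings the count of lower genes lay between 3 and 6. With the largest cluster difference per gene, the difference of HTR1D was -1.02, past 2-fold. Of the 13 lists called apart, 10 kept that call under all settings run. Subtraction of the median difference shifts a list and its random lists alike, so it could not change a call. The mean and the largest difference of a gene's clusters alter only the 345 genes with more than 1 cluster. The NCK1-AS1 locus list, inside the range as reported, fell below it with 32 added (median -0.032, percentile 1.74). The hypoxia and glycolysis median ran from -0.38 to -0.27 (-0.27 with 32 added), that of epithelial adhesion from -0.27 to -0.14 that of ribosomal proteins from 0.17 to 0.24 and that of silent genes from 0.023 to 0.15. The interferon-stimulated list turned to 0.28 over 3 genes, above the random range, with the filter at the 75th percentile, and it was inside the range with both levels at or above the median (0.080) and without dim members. The Wnt and Notch list lost its call under these 3 filters and stood at 0 at the 75th percentile. The unfolded protein list lost its call under 4 settings: the mean and the largest difference of a gene's clusters, the 75th percentile, and without equal-value genes. Its median moved only at the 75th percentile, to 0.044. Under the others it stayed at 0.080 over the same 31 members, none of them at equal values, and only the random lists changed. The basal squamous median moved to -0.29, -0.23 and -0.23 under the 75th percentile, the both-levels and the dim-member filters, and that of matrix proteases and invasion to -0.23, -0.17 and -0.15, below the random range. At the 75th percentile p53 targets moved to -0.078 and NF-kB targets to -0.13. Squamous differentiation moved to 0.039 with 32 added. The filters leave out dim genes and adding 32 shrinks dim differences by construction; the cause of the other moves was not tested. No background level was used here, so whether dim members were expressed is not known.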

Other observations

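Gene families defined by symbol were all chosen after the list results were seen, and families from the translation and protein turnover machinery stood above matched random lists. Mitochondrial ribosomal proteins had a median of 0.16 (percentile 100), with 65 of 74 higher, among them MRPS7 at 0.36 and MRPS21 at 0.35. Nucleolar ribosome assembly factors had a median of 0.15 (percentile 100), with 35 of 40 higher, among them NOP10 at 0.49, NOP16 at 0.33 and BOP1 at 0.29. Proteasome subunits had a median of 0.10 (percentile 99.96), with 29 of 36 higher, led by the catalytic subunits PSMB6 at 0.40 and PSMB5 at 0.37. NADH dehydrogenase subunits, which share members with the oxidative phosphorylation list, had a median of 0.16 (percentile 100), translation initiation factors 0.079 (percentile 99.7) and collagens, 6 of 41 on a list, 0.11 (percentile 99.3), or 0.063 after removal of the level trend. Matched by symbol, the initiation factor family also holds kinases such as EIF2AK3, the repressors EIF4EBP1 and EIF4EBP2, and pseudogenes such as EIF4A1P2. RNA polymerase subunits had a median of 0.085 at percentile 98.6, but lay inside the range after quantile normalization (percentile 97.2) and after removal of the level trend (percentile 96.3). The 501 zinc finger genes had a median of -0.014 at percentile 0, or -0.040 after quantile normalization and -0.061 after removal of the level trend, and one of -0.065 over the 293 at or above the median gene level. Transcript length and GC content were not analysed here for any family.

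Integrins, the matrix receptors, had a median of -0.087 over 19 genes at percentile 0.5, and of -0.23 over the 10 at or above the median gene level, with ITGB4 at -0.57, ITGA5 at -0.50 and ITGB1 at -0.32. Of the 19, 7 are on the basal squamous or the matrix list, so the family is not separate evidence. Procollagen-modifying and cross-linking enzymes as a family were inside the range, with a median of 0 at percentile 39.5, although PLOD2 at -0.72, LOXL2 at -0.70 and LOX at -0.48 were lower. Of genes outside these families, singled out after their values were seen, CAV1, a coat protein of caveolae, stood at -0.74. Also singled out in this way were the pseudogenes AK4P3 at -0.63 and OCLNP1 at -0.59, whose parent genes AK4 and OCLN stood at -0.39 and -0.44.

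Of the tests that follow, 4 were chosen only after the result was seen: other cell types as the source of the CDH1 difference, fibroblasts, leukocytes or endothelial cells in the culture, the silent genes against the ribosomal list, and the equal values by level. The size of the olfactory receptor median against that of the silent list was also compared only after both were seen, and the list without shared members and the random lists of protein-coding genes were alternatives added after the data were seen. The hypoxia and glycolysis list was lower in the knockdown, and its 22 measured HIF-responsive members without glycolytic enzymes, a part of the list and no separate evidence, had a median of -0.42. A family of 16 glycolytic enzymes, 12 of them on the list, had a median of -0.097 at percentile 3.02, inside the range, but at 0.52 after quantile normalization and 1.07 after removal of the level trend. A level-dependent difference between the arrays is argued against by the list median of -0.36 after that trend was removed. The random lists matched on level already had a median of 0, so the removal could change little. The 29 members on no other list had a median of -0.36, so the list median did not rest on shared members. With 32 of 34 members lower, leaving out so few could not have brought it near 0. The oxygen, density or medium of the 1 culture per arm and the knockdown cannot be told apart, because there was 1 array per group. If the control was wild type, as 1 label has it, transduction and puromycin selection cannot be told apart from the knockdown either.

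The epithelial adhesion list was lower as well, and the level trend is argued against by its median of -0.23 after removal of the trend. Its random lists matched on level already had a median of 0.0095, so the removal could change little. A cell type lacking the listed genes, in a share large enough to account for CDH1, would lower the other members about as much. Yet their median without CDH1 was -0.22, against -1.26 for CDH1. This does not bear on another epithelial type that keeps the other members, which stays open. Fibroblasts, leukocytes or endothelial cells would bring their own transcripts, but the highest median of the 3 marker lists was 0.066 and 0 of their 68 measured genes were at least 2-fold higher. Desmosome genes, 5 of 14 on the list and 9 on any list, had a median of -0.0071 (percentile 17.2) and of -0.20 over the 7 at or above the median gene level, while tight junction genes, 8 of 38 on the list, had medians of 0.016 (percentile 50.9) and -0.0017, the former turning to -0.024 after removal of the level trend. The selection of cells, the culture and the knockdown stay open and untested with 1 array per group.

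The ribosomal protein list was higher, with a median of 0.22 after the level trend was removed, which argues against that trend as the whole cause. Its random lists matched on level already had a median of -0.0043, so the removal could change little. Transcript length and GC content stay open. The silent tissue-restricted list was higher too, and random lists of protein-coding genes left it at percentile 99.81, which argues against non-coding clusters in the random lists. An offset shared by genes not expressed in cervical cells stays open for the silent list: 360 olfactory receptors outside it lay at percentile 100, but their median was 0.041 against 0.10 for the list, 0.012 against 0.072 after quantile normalization and 0.015 against 0.048 after removal of the level trend, and the 3 at or above the median gene level had a median of -0.048. The 87 keratin-associated genes had a median of 0.13. Whether such an offset carries the ribosomal list cannot be told apart from a change in those genes, because the silent median of 0.10 lay neither near 0 nor near 0.23. After removal of the level trend it was 0.048, and its 12 members at or above the median gene level, all dimmer than the median ribosomal gene, had a median of 0.12 over a range from -0.04 to 0.38. As reported above, only 6 of the 12 reached that level on both arrays, and the filter favours higher values for the others.

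ALDH1A3, RARRES1 and DHRS3, the last singled out after its value was seen, stood at -0.96, -0.84 and -0.70, and all belong to retinoid metabolism or response. A lower retinoid response was taken to call for 27 other retinoid genes to lie below the random range. They lay at percentile 77.8 with a median of 0.058, so that prediction was not met. The set was not limited to genes that respond to retinoids, since it holds receptors such as RXRA. Only 15 of the 27 were at or above the median gene level, so the question stays undecided.

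The share of clusters with equal values in the brightest of 5 level groups was 0.126 of that in the dimmest, which does not decide whether coarse steps of dim probes produce them.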
